A study of Homo sapiens with 8 samples.

How the data were processed

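RNA sequencing libraries of total RNA from SW480 (1), SW620 (1), SW620 with a FOXA2 hairpin (3) and SW620 with a control hairpin (3) were analysed from deposited tables with 1 table per library. The labels name a directional library kit; whether strand was used in counting is not given in the sources used here. Each deposited table gives, for 42713 genes with versioned Ensembl identifiers and symbols, raw counts, a length and RPKM values. The authors' RPKM values equal the count scaled by the listed length and by the table's total, for 100% of genes above 20 counts within a relative tolerance of 1e-04. The submitters' processing notes name HOMER and the hg19 build without saying what each was used for, and the aligner, the counting tool and the gene annotation are not given in the sources used here. The deposited counts were used here, and the RPKM values served only for that check.

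The tables held 40693 symbols, of which 256 were repeated, and the entry with the highest summed count stood for its symbol. Total counts ran from 7478411 to 95935350, and a limit of 3 counts corresponds to 0.0313 CPM in the deepest library and 0.401 CPM in the shallowest. Between replicates of the same group, chi-square per degree of freedom was 1.67 to 4.59, so spread exceeded counting noise. Its highest values involved replicate 1 of each group.

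The hairpin libraries were compared, 3 against 3, with the edgeR 4.0.16 quasi-likelihood test (robust, two-sided) under R 4.3.3, with TMM scaling and the default expression filter, and Benjamini-Hochberg adjustment over all genes at 0.05. The SE of a log2 fold change is its size divided by the square root of F. The biological coefficient of variation was 6.59%. There were 22 gene lists, tested by camera in limma 3.58.1 with a preset correlation of 0.01 and adjusted over the lists, for lists of at least 5 tested genes and without FOXA2, and the tests were repeated with an estimated correlation. The tables list TIGAR under the symbol C12orf5. The untreated lines were compared without a test, as the log2 ratio of TMM-scaled CPM with a pseudocount of 1, for genes with at least 20 counts in the higher library and a threshold of 4-fold. A list's median was placed among 10000 random lists matched in 20 expression bins. Single ratios carry exact 95% intervals, and a fold against 0 counts is a lower bound from 3 counts in that library. Genes at least 4-fold apart between the lines were then tested by camera in the hairpin libraries.

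Lists, tests and the rule for named genes were fixed before the data were examined. The rule took fixed transcription factors, among them FOXA1, FOXA2, FOXA3 and HNF4A; the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 2 and groups that did not overlap; and up to 3 genes per list by p. It also took the 10 genes highest in each line with at least 100 counts, up to 3 genes per list outside percentiles 2.5 to 97.5, and up to 5 genes per cell-line set.

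Gene locations, hairpin sites and 3' UTRs came from GENCODE v29 on GRCh38, a different build from that in the submitters' notes. Every 7-base sequence present in the 3' UTR of at least 50 genes was ranked by a z score. The score was the mean adjusted log2 fold change of its genes, times the square root of their number, divided by the SD over genes. Log2 fold changes were limited to 2 in either direction and adjusted for UTR length and GC content by polynomials of degree 3. Sites, Fisher's exact test and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The permutation test and the splits of the hairpin libraries used R.

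Alternatives covered scaling (DESeq2 1.42.0 size factors, total counts), filter, test (DESeq2 Wald, limma-voom), thresholds, repeated symbols, a replicate block, each hairpin library left out in turn, camera with an estimated correlation or on ranks, the pseudocount, the count minimum and the fold that defined the cell-line sets. Correction for length and GC content, thinning to the shallowest library, and removal of genes with a 3' UTR site were added after seeing the data. The methods were tested on simulated data of the same size. With 50 genes changed at each fold, edgeR recovered 12 at 1.25-fold, 32 at 1.5-fold, 39 at 2-fold and 48 at 4-fold, with 14 unchanged genes called. Camera called 10 of 10 lists shifted by 0.3 and 0 of 30 unshifted lists. The simulated genes varied independently of each other, so this could not check the preset correlation. For the untreated lines, 10 of 10 lists shifted by a log2 ratio of 1 and 7 of 190 unshifted lists fell outside the central range. That shift is larger than every list median reported for these lines, so smaller shifts were not checked. The ranking placed 17, 20 and 20 of 20 planted sites in the lowest 1% at shifts of -0.05, -0.1 and -0.2.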

Results

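Gene expression was measured by RNA sequencing in SW480 and SW620, established human colorectal cancer lines that the labels place at Dukes' stages B and C. The series title concerns reprogrammed transcription and spread of colorectal cancer to the liver. FOXA2 encodes a pioneer transcription factor of endoderm and liver. The data held 1 library of untreated SW480, 1 of untreated SW620, 3 of SW620 with a hairpin RNA against FOXA2 (shFOXA2) and 3 of SW620 with a control hairpin (shNC). The hairpins were delivered by lentivirus and the cells were selected with puromycin. Total counts over genes were 72323510 in SW480 and 95935350 in SW620. They were 12068790, 7478411 and 10012840 in shFOXA2 replicates 1 to 3, and 13076570, 12941090 and 12133650 in shNC replicates 1 to 3. Mitochondrial genes took 11.7% of counts in SW480 and 11.1% in SW620, against 4.46% to 4.82% in the 6 hairpin libraries, and the untreated and hairpin libraries were not compared by a test. The sources used here do not say whether the 3 libraries of a group came from separate cultures. Below, p-values of single genes measure only the spread between these libraries. Those of camera compare listed genes with other genes under a preset or estimated correlation, and that of Fisher's exact test counts genes.

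The first comparison asked what changed in SW620 when FOXA2 was lowered, starting with FOXA2 itself and related endoderm factors. FOXA2 (identifier ENSG00000125798.10) lies on chromosome 20 from 22581005 to 22585455 on the minus strand of GRCh38. Its level in CPM, the count as a share of the TMM-scaled library total, was 51.1 ± 1.86 (mean ± SD, n = 3) in shNC and 27.3 ± 4.40 (n = 3) in shFOXA2. That is 1.87-fold lower, with a log2 fold change of -0.91 (SE 0.09, adjusted p = 6.88e-10), and all 3 shFOXA2 libraries lay below all 3 shNC libraries. A two-sided exact permutation test on this gene gave p = 0.1, the smallest value that 10 splits of 3 against 3 allow. HNF4A, a nuclear receptor of liver and gut epithelium, rose by 0.53 on the log2 scale (SE 0.07, adjusted p = 9.02e-09). FOXA3 fell by 0.42 on the log2 scale (SE 0.16, adjusted p = 0.0289), a call that was lost when shFOXA2 replicate 3 (adjusted p = 0.175), shNC replicate 1 (adjusted p = 0.106) or shNC replicate 3 (adjusted p = 0.0893) was left out. FOXA1 had a log2 fold change of 2.28 (SE 1.18, adjusted p = 0.223), which rested on shFOXA2 replicate 1. Without that library it was 0.44 (adjusted p = 0.551).

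The labels list 2 target sequences for FOXA2 and 1 for the control, and the shFOXA2 samples are titled shFOXA2_1 with a replicate number, which points to hairpin 1 without spelling it out. The target of hairpin 1, GAACGGCATGAACACGTACAT, matched the coding sequence of FOXA2 in exon 3 of 3, at 22583093 to 22583113 on chromosome 20. The target of hairpin 2, GCAAGGGAGAAGAAATCCATA, matched the 3' untranslated region (UTR) at 22581726 to 22581746. The control target, CAACAAGATGAAGAGCACCAA, matched no transcript of GENCODE v29.

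**Figure D1:**
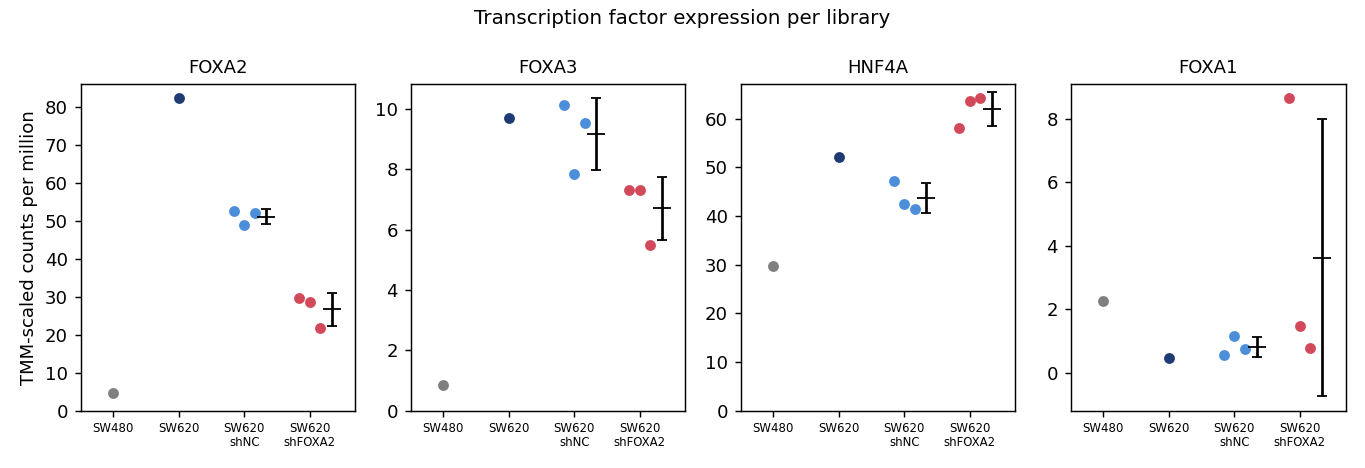
Each point is 1 library, plotted as TMM-scaled CPM on a linear axis, with a separate panel and scale for each of 4 transcription factors. Horizontal marks and bars give the mean and SD of the 3 shNC and the 3 shFOXA2 libraries; for FOXA2 the shNC libraries sit between 48.9 and 52.6, the shFOXA2 libraries between 21.8 and 29.8, SW480 at 4.63 and SW620 at 82.4.

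Among the largest rises, TNFRSF11B, the decoy receptor osteoprotegerin, went from 10.6 ± 1.78 to 56.7 ± 2.83 CPM (n = 3 each), a log2 fold change of 2.42 (SE 0.09, adjusted p = 8.14e-23). The epidermal growth factor (EGF) receptor ligand EREG went from 8.76 ± 1.19 to 37.5 ± 3.62, a log2 fold change of 2.10. AREG, another such ligand, went from 3.86 ± 0.10 to 17.7 ± 1.66, and its neighbouring copy AREGB gave nearly equal values, so reads of the pair cannot be assigned with certainty. ANXA1, a phospholipid-binding protein, went from 38.6 ± 2.08 to 161 ± 7.79, a log2 fold change of 2.05. The other largest rises were the hemidesmosome collagen COL17A1 (2.27), the lysophosphatidic acid receptor LPAR6 (2.15), the growth factor carrier FGFBP1 (2.05), the membrane protein EMP1 (1.90) and the keratin KRT6A (1.88), which shares long stretches of sequence with KRT6B and KRT6C.

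Among the largest falls, the Notch ligand DLL4 went from 13.9 ± 0.96 to 2.97 ± 0.54 CPM, a log2 fold change of -2.20 (SE 0.16, adjusted p = 9.28e-15). TXNRD1, cytosolic thioredoxin reductase, went from 181 ± 9.42 to 43.8 ± 1.00, a log2 fold change of -2.04 (SE 0.05, adjusted p = 4.68e-30). SMARCD2, a subunit of SWI/SNF chromatin remodelling complexes, went from 119 ± 6.15 to 33.2 ± 1.69, a log2 fold change of -1.83. The remaining large falls were NXT2 (-2.19), the secreted matrix protein SMOC2 (-2.01), adenosine deaminase ADA (-1.82), the LIM protein CSRP2 (-1.79), ZNF395 (-1.75), the clathrin adaptor subunit AP1M1 (-1.75) and the scaffold CARD10 (-1.74). NXT2, TXNRD1, SMARCD2, ADA, AP1M1 and CARD10, 6 of these 10 genes, hold AACACGT or ACACGTA in their annotated 3' UTR. Both are 7-base stretches of the hairpin 1 target, and they were picked after all 7-base sequences had been ranked in these data. None of the 9 genes with the largest rises that have an annotated 3' UTR holds either stretch. Over all 12890 genes searched the share with either was 5.38%, so their absence from 9 genes says little.

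Of 16100 genes tested with edgeR, 6280 (39.0%) passed an adjusted p of 0.05, 3095 higher and 3185 lower in shFOXA2. Most changes were small. The median absolute log2 fold change over the genes that passed was 0.36, and 238 of them rose and 217 fell by at least 2-fold. The groups did not overlap for 48.7% of tested genes, where chance gives 10%. In shFOXA2 replicate 1, 62 genes had at least 30 counts and at least 4 times the CPM of any other hairpin library, against 14 in shNC replicate 1 and 0 in each of the other 4. Without shFOXA2 replicate 1, 5783 genes passed, and 5422 of the 6280 stayed among them.

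Genes of cell division fell together. In the G2/M and mitosis list, 24 of 30 tested genes fell and 0 rose (26 and 0 adjusted over the list alone), with a median log2 fold change of -0.36. MKI67, a proliferation marker, went from 1084 ± 63.9 to 456 ± 14.5 CPM, and the mitotic spindle genes KIF2C (-0.73) and NUSAP1 (-0.59) also fell. In the DNA replication list, 29 of 32 fell and 0 rose (29 and 0 adjusted over the list alone), with a median of -0.32, among them the helicase subunits MCM3 (-0.58) and MCM7 (-0.43) and the licensing factor CDC6 (-0.58). Tested as groups with camera, both lists gave an adjusted p of 3.11e-12 with a preset correlation. With an estimated correlation the adjusted p was 0.126 for G2/M and mitosis and 0.253 for DNA replication.

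The mesenchymal transition list had 15 genes higher and 2 lower of 27 (16 and 2 adjusted over the list alone), with a median log2 fold change of 0.68 and adjusted p = 1.49e-06 by camera, or adjusted p = 0.120 with an estimated correlation. Besides ANXA1, the transforming growth factor receptor TGFBR2 rose by 1.19 on the log2 scale, from 110 ± 6.41 to 252 ± 7.28 CPM, whereas the calcium-binding protein S100A4 fell by 1.01 on the log2 scale and TGFBI also fell. CDH2 (3.61), CTGF (2.46), LOX (2.01) and FN1 (1.67), named after their values were seen, had high fold changes that did not pass and that came mainly from shFOXA2 replicate 1. Without that library they were 0.65, 0.85, -0.68 and 0.58, and the list had a median of 0.66 and adjusted p = 1.43e-07.

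Immediate early genes, which respond within minutes to growth signals, were mostly higher, with 16 of 23 up and 3 down (17 and 3 adjusted over the list alone), a median of 0.26 and adjusted p = 0.000823 by camera, or adjusted p = 0.186 with an estimated correlation. The phosphatase DUSP5 rose from 24.1 ± 0.96 to 57.3 ± 1.60 CPM and the transcription factor EGR2 rose by 0.88 on the log2 scale, while ETV5 fell by 0.61, and JUN and NR4A1 fell. The colon epithelium list had 9 genes higher and 2 lower of 18 (10 and 2 adjusted over the list alone), with a median of 0.41 and adjusted p = 0.0143 by camera, or adjusted p = 0.253 with an estimated correlation. The mucin MUC13 (0.89) and the gut transcription factors KLF4 (0.86) and CDX2 (0.69) rose, and the adhesion proteins CEACAM5 (-0.98) and CEACAM6 (-0.60) fell.

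The 3 liver lists were not called. Of 16 genes for liver plasma proteins, FGA, a fibrinogen chain, rose (1.82) and albumin, ALB, fell (-1.04), with a median of 0.24 and adjusted p = 0.829. Counts were low for both, at 0.472 and 2.33 CPM in shNC, and the ALB call was lost without shFOXA2 replicate 3 (adjusted p = 0.0681) or shNC replicate 2 (adjusted p = 0.158). APOB, the main apolipoprotein of liver and gut lipoproteins, had 1882 counts in shFOXA2 replicate 1, 41 to 65 in the other hairpin libraries and 0 in both untreated libraries, and without that library the list's median was -0.12. Of 17 liver metabolic genes, 3 were higher and 1 lower (2 and 0 adjusted over the list alone; median 0.24, adjusted p = 0.303), led by the cytochrome CYP3A5 (0.92) and the tyrosine catabolism enzyme FAH (0.70). CYP27A1, a bile acid synthesis enzyme, fell by 0.61 on the log2 scale, a call lost without shFOXA2 replicate 2 (adjusted p = 0.208), shFOXA2 replicate 3 (adjusted p = 0.0606), shNC replicate 2 (adjusted p = 0.183) or shNC replicate 3 (adjusted p = 0.0785). CYP3A5 holds a 3' UTR site for the 7-base stretches given above. Of 16 liver and endoderm transcription factors other than FOXA2, 2 were higher and 4 lower (2 and 4 adjusted over the list alone; median 0.01, or -0.08 without shFOXA2 replicate 1; adjusted p = 0.918), including HNF4G (-1.37) and CEBPB (-0.89).

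Other epithelial lists moved in both directions and were not called. Wnt targets had 7 genes higher and 9 lower of 25 (7 and 10 adjusted over the list alone; adjusted p = 0.303). The stem cell factor ASCL2 (-0.91) and the receptor KREMEN1 (-1.36, with a 3' UTR site) fell, and the pseudoreceptor BAMBI (0.75) rose. Epithelial adhesion genes had 9 higher and 9 lower of 29 (10 and 10 adjusted over the list alone; adjusted p = 0.544), with a median of -0.05 but a mean of 0.09 and a test that pointed up. The hemidesmosome integrin ITGB4 (0.68) and the desmosome cadherins DSC2 (1.68, with a site) and DSG2 (0.66) rose. Goblet and secretory genes had 4 higher and 2 lower of 14 (5 and 2 adjusted over the list alone; adjusted p = 0.544), with the kallikreins KLK10 (0.66) and KLK6 (0.24) higher and the mucin MUC1 lower (-0.83). Enteroendocrine genes had 2 higher and 3 lower of 8 (3 and 3 adjusted over the list alone; adjusted p = 0.829), with SCG2 (0.85) higher and CHGB (-0.57) and ENO2 (-0.26) lower.

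Metabolic and stress lists were not called either. Cholesterol synthesis had 9 genes higher and 4 lower of 24 (adjusted p = 0.338), with CYP51A1 (0.32) among those higher. Fatty acid metabolism had 7 higher and 6 lower of 27 (adjusted p = 0.829), with ACSL5 (1.07) and ACLY (0.40) higher and CPT1A (-0.41, with a site) lower. Glycolysis and hypoxia had 6 higher and 6 lower of 29 (adjusted p = 0.829), with a median of -0.05 but a mean of 0.16 and a test that pointed up. The upward mean came mostly from shFOXA2 replicate 1, without which the difference from other genes was 0.028, the lowest with any library left out. The glucose transporter SLC2A1 (0.69, with a site) and the hexokinase HK1 (0.44) rose and PFKP (-0.87) fell. The unfolded protein and amino acid stress list had 3 higher and 11 lower of 27 (adjusted p = 0.262), with TRIB3 (-0.70) and CEBPB lower and the chaperone HSPA5 (0.33) higher. For these 4 lists, and for the interferon, p53, histone, ribosomal, fibroblast and leukocyte lists that follow, the counts adjusted over the list alone were the same.

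Interferon response genes had 4 higher and 4 lower of 25 (adjusted p = 0.829), with ISG15 (-0.84), MX2 (-0.96) and USP18 (-0.84) lower. The p53 targets had 7 higher and 3 lower of 22 (adjusted p = 0.425), with TNFRSF10B (0.31) higher and GDF15 (-1.09) and DDB2 (-0.48) lower. Histone genes had 0 higher and 2 lower of 19 (adjusted p = 0.312), namely HIST1H1C (-0.61) and HIST1H2AC (-0.38). Ribosomal protein genes had 2 higher and 11 lower of 35 (adjusted p = 0.237), with RPL15 (0.30) higher and RPS23 (-0.26) and RPL10A (-0.22) lower. That list was called, as lower, without shFOXA2 replicate 2 (adjusted p = 0.0170), shNC replicate 2 (adjusted p = 0.0451) or shNC replicate 3 (adjusted p = 0.0403). Markers of other cell types were sparse. Of the fibroblast and endothelial markers only 5 could be tested, with COL1A1 (1.06) and LUM (0.53) higher and TAGLN (-1.04) lower (adjusted p = 0.912; median 0.53, or -0.35 without shFOXA2 replicate 1). Of 8 leukocyte markers, GZMB (3.30, from 0.157 to 1.67 CPM), LYZ (0.85) and CD4 (0.92) were higher and 0 were lower (adjusted p = 0.257).

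**Figure D2:**
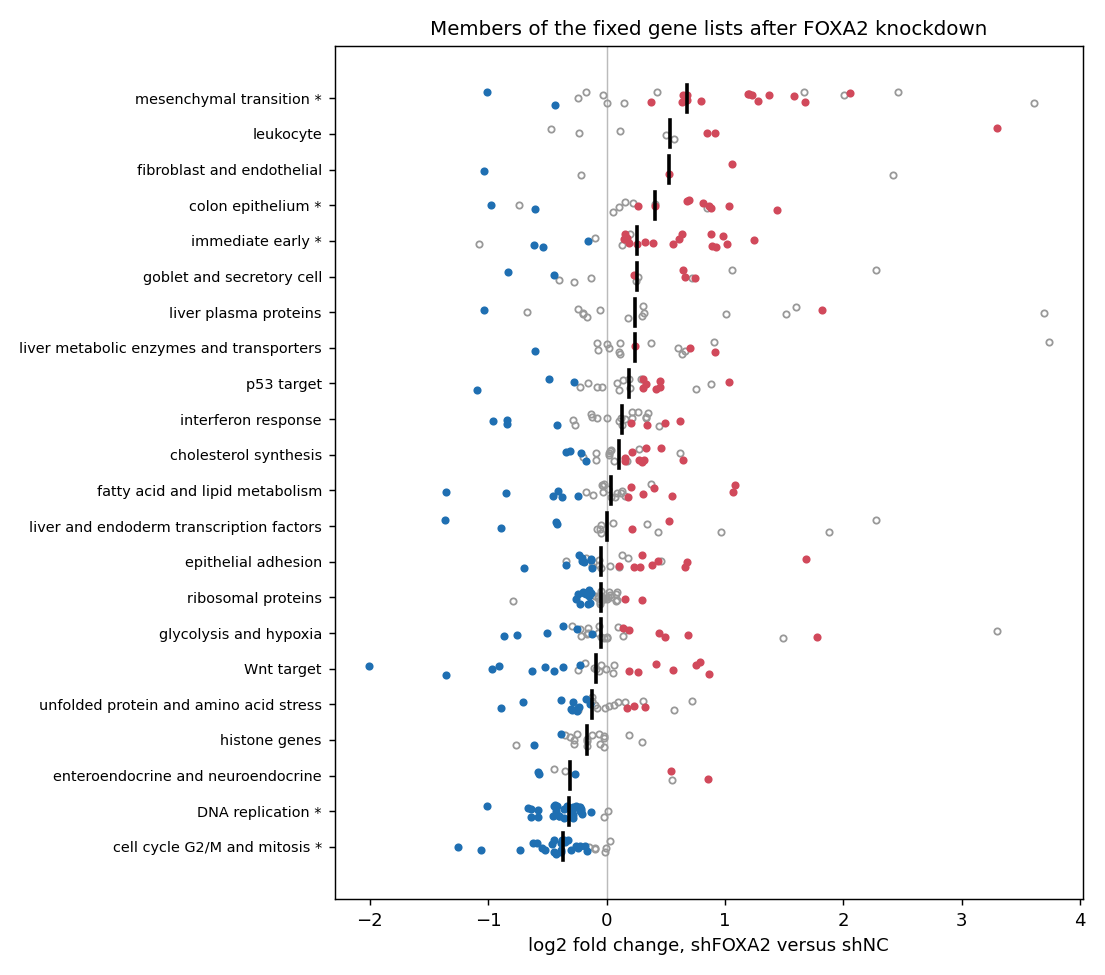
Each point is 1 tested gene of a fixed list, placed by its log2 fold change in shFOXA2 versus shNC, filled red where it was called higher, filled blue where called lower and open where it did not pass. Black bars are list medians, which run from -0.36 for G2/M and mitosis to 0.68 for mesenchymal transition, and asterisks mark the 5 lists called by camera with a preset correlation.

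The second comparison set the untreated lines side by side, with 1 library each and no test. Its intervals are exact 95% intervals of a ratio of counts, and they and the limits for counts of 0 cover counting error only. A limit of 3 counts corresponds to 0.0415 CPM in SW480 and 0.0313 in SW620 before scaling. FOXA2 had 319 counts in SW480 and 7882 in SW620, and was 18.0-fold higher in SW620 (16.1 to 20.2). FOXA3 was 11.5-fold higher (8.81 to 15.2) and HNF4A 1.78-fold higher (1.69 to 1.88). FOXA1 was 4.84-fold higher in SW480 (3.44 to 6.92), from 155 counts against 44. Of 21343 genes with at least 20 counts in the higher library, 485 were at least 4-fold higher in SW620 and 613 in SW480, together 5.14%. Those counts come from ratios with 1 CPM added to each library, which leaves FOXA1 out, whereas the folds of single genes have nothing added. With 0.1 CPM added the total was 2539.

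The genes highest in SW620 relative to SW480 included the actin-bundling protein LCP1, with 1 count against 21101 (15369-fold, 2758 to 607083), and the imprinted gene PEG10, with 0 counts in SW480 and at least 4632-fold higher in SW620. PHYHIPL was 2872-fold higher (1319 to 7826), the endopeptidase MME 1836-fold (890.9 to 4567) and the surface protein PROM1 931-fold (452 to 2317). The others were RASSF6, CNN3, SHISA9, the chemokine CXCL6 and the junction protein CGNL1. Genes highest in SW480 included the Wnt ligand WNT5A, with 0 counts in SW620 and at least 5625-fold higher in SW480, and the Wnt antagonist DKK4, 3990.2-fold higher (1833 to 10875). The basal keratin KRT5 was 156-fold higher in SW480 (148 to 164) and the EGF receptor gene EGFR 831-fold (503 to 1485). The others were NELL2, the hypoxia-inducible factor EPAS1, the cyclin CCND2, the stress-responsive ANKRD1, PHLDB2 and CCDC3.

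Several fixed lists lay outside the central 95% of 10000 random lists matched on expression. Medians and numbers of genes at least 4-fold apart use ratios with 1 CPM added. Colon epithelium genes were higher in SW620 (20 genes, median log2 ratio 0.72, or 0.74 with genes at 0 counts set to their bound, percentile 100), with CEACAM5 195-fold higher (89.4 to 532), CEACAM6 at least 262-fold and the keratin KRT20 at least 194-fold. Of its genes 4 were at least 4-fold higher and 2 as much lower, including CDX2, 11.2-fold higher in SW480. Goblet and secretory genes were also higher (14 genes, median 0.51, percentile 98.7), with the trefoil peptide TFF3 475-fold, the mucins MUC5AC 73.3-fold and MUC1 5.89-fold. Wnt targets (26 genes, median 0.47, percentile 99.97) were led by SMOC2, at least 1105-fold higher, the stem cell receptor LGR5, 43.5-fold, and KREMEN1, 8.74-fold, but 4 genes including DKK4 were at least 4-fold lower against 8 higher. Epithelial adhesion genes (30 genes, median 0.42, percentile 99.99) were led by PROM1, KRT7 at 16.2-fold and the transcription factor EHF at 9.41-fold, with 4 genes at least 4-fold higher and 1 lower. Liver plasma protein genes (20 genes, median 0.55, percentile 99.99) included the coagulation factor F5, with 2 counts in SW480 and 304 in SW620 (111-fold, 30.4 to 918), the complement factor C3, 2.37-fold, and ALB, 19.7-fold (8.22 to 61.5), but SERPINA1, from 5193 counts against 1683, was 4.24-fold higher in SW480 (4.01 to 4.48), and the list had 1 gene at least 4-fold higher and 1 lower. With a minimum of 100 counts this list was at percentile 95.4, inside the central range.

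Lists lower in SW620 included mesenchymal transition (27 genes, median -0.55, percentile 0.020), with CYR61 24.3-fold and the adhesion receptor CD44 8.98-fold higher in SW480. It was split, with 6 genes at least 4-fold lower and 4 higher, the latter including ANXA1 (7.48-fold) and TGFBR2 (4.79-fold). Liver metabolic genes were lower in SW620 (22 genes, median -0.46, percentile 0.070), with UGT1A1 42.5-fold and ASS1 3.05-fold higher in SW480; UGT1A1 shares exons with its neighbours. Against that direction, the transporter ABCC2 was 371-fold and the cytochrome CYP2E1 29.9-fold higher in SW620. Cholesterol synthesis (24 genes, median -0.56, percentile 0.020) was led by STARD4 at 6.39-fold, INSIG1 at 5.19-fold and CYP51A1 at 5.02-fold. Unfolded protein and amino acid stress genes (27 genes, median -0.67, percentile 0) included VLDLR at 3.97-fold, ATF3 at 3.78-fold and ASNS at 3.07-fold. G2/M and mitosis genes (30 genes, median -0.36, percentile 0.470) included AURKA at 2.16-fold and BUB1 and CENPA at 1.95-fold each, with 0 genes at least 4-fold apart either way. Against that direction, MKI67 had 79582 counts in SW480 and 157128 in SW620, more than the difference in depth gives. The remaining 12 lists lay inside, at percentiles of 88.1 for liver and endoderm transcription factors, 62.7 for enteroendocrine, 96.8 for DNA replication, 73.5 for interferon, 36.2 for p53, 65.9 for fatty acid, 13.2 for glycolysis, 11.8 for immediate early, 39.0 for histone, 97.0 for ribosomal, 43.1 for fibroblast and 17.4 for leukocyte genes. With a minimum of 100 counts, interferon (98.9), leukocyte (98.4) and ribosomal genes (97.6) moved to the upper side, as did DNA replication (97.51) with 0.1 CPM added.

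The third comparison asked whether genes that set SW620 apart from SW480 moved with FOXA2 in the hairpin libraries, which share no library with the untreated pair. Of 372 tested genes at least 4-fold lower in SW620, 137 (36.8%) rose and 20 (5.38%) fell in shFOXA2, with a median log2 fold change of 0.32. The set was higher than other genes by camera (p = 2.9e-07, or p = 0.00209 with an estimated correlation). Every other split of the hairpin libraries, 3 against 3, also gave this set a camera p under 0.05, from 2.36e-05 to 0.0112. Each of those splits mixed both hairpin groups and kept part of their difference, so they are no null for this set. TNFRSF11B, the mitochondrial phosphatase PDP1 (1.58), the metalloprotease ADAM19 (1.22) and SLC2A14 (1.77), near-identical to SLC2A3, rose, and the myosin MYH7B fell (-1.48). Of 474 tested genes at least 4-fold higher in SW620, 88 (18.6%) rose and 182 (38.4%) fell, with a median of -0.11 and p = 0.00412 by camera, a call lost with an estimated correlation (p = 0.138). The 5 genes of this set with the smallest p were mostly risers: ANXA1, TGFBR2, the caveolae protein CAV1 (1.43) and the noncoding RNA RP11-401P9.4 (1.00) rose, and the inhibin subunit INHBB (-0.90, with a 3' UTR site) fell. Among the other 15253 genes, 18.8% rose and 19.6% fell.

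**Figure D3:**
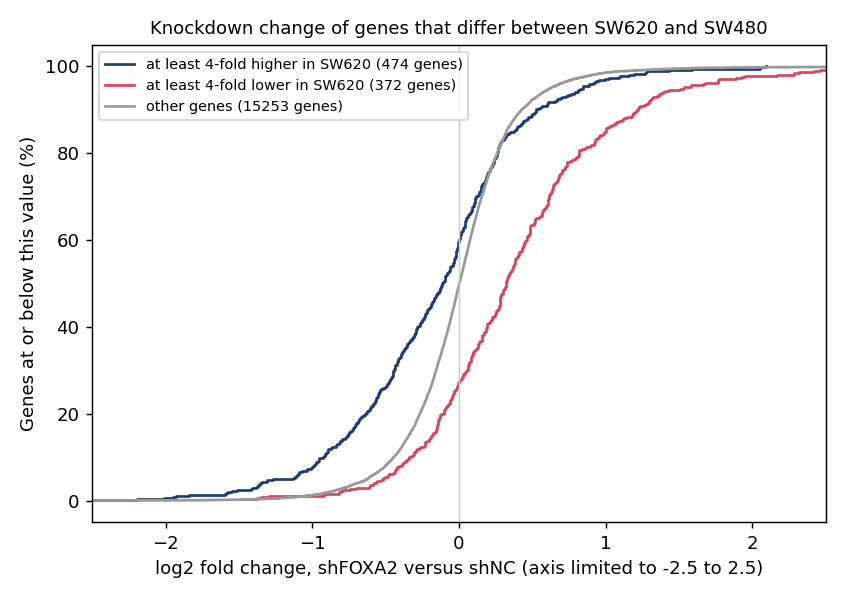
Curves give the percentage of genes at or below each log2 fold change in shFOXA2 versus shNC, with the horizontal axis limited to -2.5 to 2.5, for genes at least 4-fold higher in SW620 than in SW480 (474 genes), at least 4-fold lower (372 genes) and all others (15253 genes). The curve of genes lower in SW620 lies to the right of the others through most of its range, with a median of 0.32, and that of genes higher in SW620 lies to the left in its lower part, with a median of -0.11.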

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

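The correction for length and GC content, the thinning of every library to the shallowest and the removal of genes with a hairpin 1 site or no annotated 3' UTR were chosen only after the data were seen. FOXA2 stayed lower in all 16 alternatives run, from -1.01 to -0.79 (adjusted p from 3.7e-33 to 1.07e-06). The number of changed genes was 5299 to 5872 with each hairpin library left out, 4901 by DESeq2, 6248 by limma-voom, 4725 at an adjusted p of 0.01, 5946 after the length and GC correction, 5594 after thinning and 5330 of 12197 without the site genes. It was 455 when a 2-fold change was also required, since that condition drops smaller changes. Genes lower in SW620 lay above other genes by 0.26 to 0.50 (p from 8.4e-08 to 0.00209) in all 16 alternatives. Genes higher in SW620 lay below other genes by -0.26 to -0.11 in all 16; with an estimated correlation the value was -0.18 but p = 0.138, because only the assumed correlation differed. That setting also left 0 of the 5 list calls, while leaving out a library gave 5 to 6 and no filter gave 7. Beside the count of 0, 3 lists had an unadjusted p under 0.05 in that setting, and camera on ranks is among the settings that kept all 5. In the untreated lines, 2539 genes were 4-fold apart with a pseudocount of 0.1, which shrinks the ratios of weakly expressed genes less, and 3595 at 2-fold, which admits smaller differences. There, 10 to 12 lists lay outside the central range.

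Reversals concerned only lists that were not called. Without a filter, the mean difference from other genes was -0.072 for goblet and -0.103 for interferon genes, and without site genes it was -0.0059 for epithelial adhesion, -0.013 for interferon and -0.040 for fatty acid genes; the cause was not tested. With each library left out in turn it ran from -0.024 to 0.80 for liver plasma proteins, -0.15 to 0.34 for liver and endoderm transcription factors, -0.077 to 0.019 for enteroendocrine, -0.033 to 0.036 for interferon, -0.013 to 0.032 for fatty acid and -0.16 to 0.83 for fibroblast and endothelial genes. Among named genes, FOXA3 lost its call in 5 alternatives, CYP27A1 in 7 and ALB in 3, and the other calls were kept wherever an adjusted p was given. Unfolded protein and ribosomal lists became called without a filter (adjusted p = 0.0345 and 0.00445). With replicate number as a block, 6139 genes passed and 5 lists were called. Deviations of same-numbered libraries from their own group means in log2 CPM correlated across genes at -0.0044, -0.047 and -0.0051, so the numbers gave no sign of pairing. Depth limits the genes near 1 CPM, where FGA, GZMB and ALB lie.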

Other observations

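The 8 gene lists given first, the 4-fold rule for genes in excess, and the tests of hepatocyte transcripts, of shares in other libraries, of the hypoxia list, of shifted hairpin windows and of the share of falling genes with a site were chosen only after the result was seen. Thinning and the length and GC correction were added after the data were first seen, with their bounds set before their own results.

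Known targets of YAP and TAZ, co-activators that respond to cell shape and contact, were mostly higher in shFOXA2. Of 21 tested genes 13 rose and 2 fell, with a median log2 fold change of 0.50 and adjusted p = 6.43e-06 over the 8 lists, or adjusted p = 0.0453 with an estimated correlation. The ectonucleotidase NT5E (2.53), TGFB2 (1.58), the caveolin CAV2 (1.02), tissue factor F3 (0.99) and MYOF (0.81) rose, and TEAD1 (-0.19) and ARHGAP29 (-0.44) fell. AXL and TGFB2 also stand in the mesenchymal transition list. CTGF, described above with that list, was not among the targets tested here. As a group the targets were lower in SW620 than in SW480, with a median log2 ratio of -0.71, below every matched random list (percentile 0), but CAV2 (2.16) and MYOF (2.02) were higher in SW620 and TGFB2 was nearly level (0.02).

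Subunits of mitochondrial complex I, the first enzyme of the respiratory chain, were mostly lower in shFOXA2, with 18 of 35 down and 1 up, a median of -0.15 and adjusted p = 3.78e-05, or adjusted p = 0.213 with an estimated correlation. NDUFA6 (-0.64) and NDUFA11 (-0.56) fell most. The 1 gene of the list that rose, NDUFA4 (0.12), is named for complex I but belongs to complex IV. Ligands and targets of the EGF receptor pathway had 7 higher and 2 lower of 16, with a median of 0.16 and adjusted p = 0.0150, or adjusted p = 0.213 with an estimated correlation. The receptor gene EGFR had only 15 counts (0.154 CPM) in untreated SW620, and signalling through the receptor was not measured. The ligand BTC (1.33), the transcription factor FOSL1 (1.05) and the cytokine LIF (0.81) rose, and ERBB2 (-0.28) fell. EREG and AREG, whose rise had been seen, were left out of that list, as was NDUFB6, described below, from that of complex I. The other 5 lists were not called with all libraries: basal and stratified epithelium (7 higher and 3 lower of 18, adjusted p = 0.0834, but 0.0462 without shFOXA2 replicate 1), proteasome (2 and 10 of 31, 0.114), Notch (6 and 6 of 20, 0.538), lysosome (9 and 4 of 29, 0.650) and NRF2 targets (7 and 8 of 23, 0.901). Genes named above among the largest changes were absent from these lists too. They were DLL4 (-2.20) for Notch, TXNRD1 (-2.04) for NRF2, and COL17A1 (2.27) and KRT6A (1.88) for basal epithelium.

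In shFOXA2 replicate 1, 62 genes exceeded every other hairpin library at least 4-fold with at least 30 counts, among them APOB, and shNC replicate 1 had 14 such genes and the other 4 libraries 0. The tables argue against admixed hepatocytes, since 0 of 6 abundant hepatocyte transcripts rose by more than 100 counts where APOB rose by 1823; against admixed fibroblasts, since 0 of 6 abundant fibroblast transcripts did where SPARC rose by 160; and against hypoxia of that culture, since 29 genes of the glycolysis and hypoxia list had a median difference of -0.0041 (quartiles -0.05 and 0.08), with 2 above 1. Other liver and mesenchymal genes, picked after their values were seen, were in excess, among them APOA2 (144 counts against 4 to 7), RBP4 (228 against 1 to 10), CDH2 (316 against 5 to 14) and FN1 (1082 against 156 to 219), so another kind of cell that carries them stays open as a source, as does any other change of that culture, untested. Over 12 genes nearly silent in untreated SW620, the other 5 libraries held median shares of 2.73% to 4.41% of its counts, so some of its reads may have been assigned to the other libraries, which would not explain the excess itself. Among 37 genes with names of complex I subunits, NDUFB6 stood 1.65 log2 units above the other shFOXA2 libraries while the next highest stood at 0.16. Genes that overlap shared nearly equal counts (ANG 328 and RNASE4 331, CCL15 207 and CCL14 206).

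Off-target pairing by a hairpin could add to the genes that fell: the planned test, on guide positions 2 to 8, argued against it, with the hairpin 1 sequence at percentile 7.12 and hairpin 2 at 92.9 from the lowest, and the control at 55.2 from the highest. After neighbouring start positions had been tried and the ranking seen, all 45 windows of the 3 targets were looked up, and ACACGTA and AACACGT of hairpin 1 stood at ranks 1 and 2 of 16250, while the best of hairpin 2 stood at 4158. For the genes that rose, GCACCAA of the control, at guide positions 1 to 7, stood at rank 28 from the highest, overlapping CACCAAC and ACCAACA at 1 and 2, which run past the end of the target, so a shifted control guide behind part of the rises cannot be told apart from an effect of FOXA2, as rank 28 lies between the bounds of 10 and 100 set for it. Of 693 genes with ACACGTA or AACACGT, the 2 hairpin 1 sequences, 38.2% fell against 20.8% of other genes. Among genes lower by at least 2-fold, 34 of 173 held 1 of these sites, against 7 of 200 higher by as much. The odds ratio for being 2-fold lower with a site against without was 4.48 (Fisher's exact p = 3.33e-11, with genes not independent). Direct pairing at these 2 sequences cannot be the whole cause. Of the 2802 searched genes that fell, 9.46% held 1, and 5330 genes still passed among the 12197 without a site. Yet other sequences with ACACGT, at ranks 3, 4 and 7, were not counted, and effects passed on by genes with sites stay open, untested. A guide of hairpin 1 that starts beside the assumed position, if the libraries carry that hairpin, is therefore a hypothesis for part of the falls, found and tested on the same data, and an effect of FOXA2 itself and these sites stay open together for genes such as TXNRD1 and SMARCD2.

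With FOXA2 1.87-fold lower, 1 of 10 splits of the 6 libraries, the real one, gave as many as 6280, with 0 the highest of the others by edgeR (157 to 254 at an unadjusted p under 0.05), which is too few splits for a share under 0.05. The tables argue against depth and against length or GC bias as the whole cause, since 85.4% of called genes stayed called in the same direction after thinning and 82.6% after the length and GC correction. For the lists, 6 of 10 splits called at least the 5 of the real split, and the highest other called 8. For genes higher in SW620, 3 of 10 splits gave a camera p as small as 0.00412, the smallest other being 0.000649. For genes lower in SW620, only the real 1 of 10 reached 2.9e-07, and the others gave 2.36e-05 to 0.0112. Every split thus put that set under 0.05. The other splits are no null, since each mixed both hairpin groups and kept part of their difference. FOXA2 differed by 0.13 to 0.41 log2 units in them, against 0.91 in the real split. They therefore cannot show whether a camera p is calibrated, or how many genes or lists would be called without a hairpin difference. These splits are also too few for a share under 0.05. A response of the cells to less FOXA2 and a difference between the hairpin cultures as such stay open, untested.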
